A study of Mus musculus with 8 samples.

How the data were processed

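RNA from laser-captured areas of the right testis of 4 DEHP-treated and 4 vehicle-treated mice was measured on 8 Agilent 2-colour arrays. Per the labels' protocols, RNA came from single caps of independent mice, was amplified in 2 rounds and labelled with Cy5 or Cy3. The 4 arrays with DEHP in Cy5 lay on slide 1 and the 4 with DEHP in Cy3 on slide 2, so slide and dye orientation cannot be separated.

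Mean foreground and median background intensity of each spot were deposited as scanned, with no background subtracted, per the file headers (Agilent Feature Extraction 9.5.1.1). The log10 ratio of Cy5 over Cy3 was computed by the same software from background-subtracted, dye-normalised signals, per the file headers. The authors also deposited a table of log2 ratios of DEHP over vehicle, with limma named in the labels' processing notes. Its direction and its match to spots were found from the values, and the version of limma, the background correction, the normalization and the filter behind it were not given in the sources used here.

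Each array held 45018 spots. The spike-in controls gave a slope of 0.881 to 0.931 against their known ratios and a correlation across spikes of 0.988 to 0.995. No spot was saturated (0 per array) and 154 to 209 spots per array were left out because the extraction software marked them as outliers. The share of spots well above background was 49.8% to 59.5% per channel. The number of arrays limits the precision.

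Intensities were corrected by normexp with an offset of 50, normalised by loess within each array, averaged over the spots of a probe and turned to DEHP over vehicle. The 2 arrays of a mouse pair were averaged, which cancels a dye effect and leaves 4 independent values per probe. Probes were kept if well above background in at least 4 of 8 DEHP channels or at least 4 of 8 vehicle channels. An intercept was fitted to the 4 pair means with limma 3.58.1 in R 4.3.3 (data.table in version 1.17.8, statmod in version 1.5.0), with moderated 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Probes were matched to current symbols: 22951 by accession, 6659 by symbol and 3109 by synonym, and 8455 were not matched. Probe positions are those of the design in mm7.

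The 29 gene lists were fixed before the data were examined, as were the design and the rule for named genes, and were tested by camera with a preset correlation of 0.01, with an estimated correlation, and by fry. Each gene was represented by its brightest kept probe. Named genes were up to 12 per direction past the threshold with the same sign in all 4 pairs, and since none passed, the places were filled by the smallest unadjusted p, leaving out clone-like names. Per list, the 2 members with the smallest unadjusted p were added, with 10 genes fixed by name. A gene that the rule names is not reported here. Median, mean and camera direction differed in sign for the lists of Leydig markers, endothelial and blood markers, elongating spermatid markers, fatty acid synthesis, retinoid signalling, hormone and nuclear receptors, and apoptosis.

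The fit was tested on simulated pair means with 200 of 22975 probes changed. The share recovered was 0% at 1.41-fold, 82% at 2-fold (13 false calls), 92.5% at 2.83-fold (7 false calls) and 97.5% at 4-fold (13 false calls). The simulated probes were independent, with the same variance in all pairs, so these shares need not hold for the data. With independent genes, camera called a list in 0 of 20 runs without a change and called a list shifted by 0.1 in 20 of 20 runs. That test held no correlation between genes, so it does not cover the preset correlation in correlated lists.

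Mouse pairs come from the arrays' labels, and the dye-swapped arrays of the same mice correlated across probes by 0.544 to 0.717. Alternatives covered background correction, normalization, the filter, the treatment of pairs and dyes, array weights, the variance model, the set test, the probe per gene, each pair left out in turn, and the authors' deposited ratios. Tests for the closing section used 10000 random lists matched on mean intensity in 100 bins.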

Results

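The series asked how di-(2-ethylhexyl) phthalate (DEHP), a plasticiser and a known peroxisome proliferator in rodents, affects Sertoli-cell-rich areas of the adult mouse testis. Sertoli cells are the somatic cells of the seminiferous tubule that carry and feed the germ cells. Adult male C57BL/6J mice received DEHP at 200 mg/kg/day in corn oil, or corn oil alone, by gavage for 21 days, with 4 mice per group. RNA from laser-captured areas of the testis was amplified and compared on 8 Agilent arrays with 2 colours each. Each of 4 DEHP mice was paired with 1 vehicle mouse, and each pair was hybridised in both dye orientations. Pairs are named by the DEHP mouse: pair 1 held DEHP mouse 1 and vehicle mouse 2, pair 2 held DEHP mouse 2 and vehicle mouse 3, pair 3 held DEHP mouse 3 and vehicle mouse 4, and pair 4 held DEHP mouse 4 and vehicle mouse 1. Per array and channel, 49.8% to 59.5% of spots were well above background. Of 41174 probes, 22975 for 16969 genes were tested. The number of arrays and mice limits the precision.

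No single gene passed the test between DEHP and vehicle. In limma, 0 of 22975 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.902; 1054 had an unadjusted p under 0.05. As groups, genes for ribosomal proteins, the structural proteins of the ribosome, had a median log2 ratio of 0.10, genes of oxidative phosphorylation, the mitochondrial respiratory chain, had 0.081, and Sertoli cell markers had 0.039. These were 3 of 29 gene lists called by camera with its preset correlation, with adjusted p of 3.15e-10, 0.000547 and 0.0448 over 4 pairs. With an estimated correlation, all 3 calls were lost (adjusted p = 0.865 each), and limma's fry called 0 of the 29 lists (adjusted p = 0.82 for each of these 3).

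Named next are the 12 genes per direction with the smallest p and the same sign in all 4 pairs, none of which passed (adjusted p 0.902 in limma for each). The values are mean log2 ratios of DEHP over vehicle ± SD over n = 4 pairs. Tmed6, of a family of cargo receptors of the secretory pathway, had 0.45 ± 0.23, and Mpo, the peroxidase of neutrophil granules, had 0.40 ± 0.17. Rhox3a (Rhox3 in the files), a homeobox gene of the reproductive X-linked cluster, had 0.39 ± 0.11 (chromosome X, 32015422 to 32017357, mm7). Ssxb2 had 0.40 ± 0.15, and both of these genes have near-identical copies that a probe could share. Etd, named for embryonic testis differentiation, had 0.36 ± 0.10 (chromosome X, 48535689 to 48535748, mm7). Acot13 (Them2), an acyl-CoA thioesterase of mitochondria, had 0.39 ± 0.20, and pair 1 stood apart from the others. Trmt10b (Rg9mtd3), a tRNA methyltransferase, had 0.39 ± 0.15, Lsm1, of the mRNA decapping machinery, had 0.32 ± 0.14, and Dhh, the Sertoli-cell hedgehog ligand, had 0.26 ± 0.079. Iqcf3 had 0.24 ± 0.088, and Dld, the dihydrolipoamide dehydrogenase of mitochondrial complexes, had 0.21 ± 0.054. Sprr2a1 had 0.35 ± 0.17, and its other probe had the opposite sign.

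The 12 genes with lower ratios did not pass either. Upf3a, of nonsense-mediated decay, had -0.38 ± 0.094 (chromosome 8, 13772777 to 13772836, mm7), Hnrnpr (Hnrpr) had -0.35 ± 0.086, Ddx17, an RNA helicase, had -0.28 ± 0.073, and Caprin1 (Gpiap1), an RNA granule protein, had -0.38 ± 0.17. Etfb, the beta subunit of the electron transfer flavoprotein of fatty acid oxidation, had -0.51 ± 0.21 (chromosome 7, 39633278 to 39633337, mm7). Slc25a25, a mitochondrial ATP-Mg/phosphate carrier, had -0.25 ± 0.047, and Fbxl12, a ubiquitin ligase subunit, had -0.45 ± 0.20. Lypd4 had -0.37 ± 0.14, Cfap45 (Ccdc19), a protein of motile cilia, had -0.34 ± 0.086, and Dido1 had -0.33 ± 0.11. Trip11, a Golgi protein, had -0.33 ± 0.12, and 1 of its 3 other probes had the opposite sign. Actr5, of the INO80 chromatin remodeller, had -0.20 ± 0.014. Annotation of exons in mm7 was not available.

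**Figure D1:**
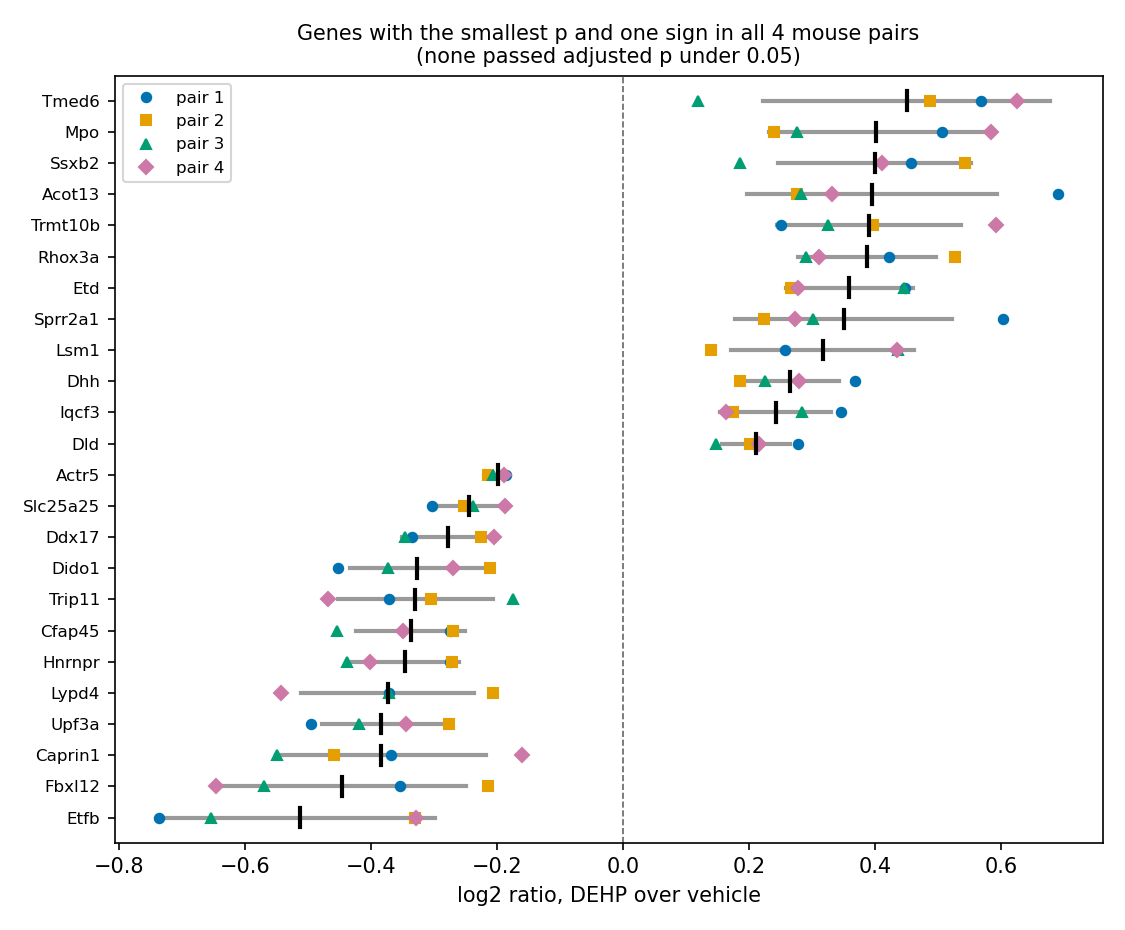
Log2 ratio of DEHP over vehicle (x axis) for the 24 genes with the smallest p and 1 sign in all 4 pairs. Points are the 4 mouse pairs, the black tick is their mean and the grey bar is 1 SD; Etfb had the lowest mean at -0.51 and Tmed6 the highest at 0.45, and none passed adjusted p under 0.05.

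Of the ribosomal protein genes, 72 of 79 measured members had a positive mean ratio and 16 were higher in all 4 pairs, with medians of 0.20, 0.037, 0.17 and -0.026 in pairs 1 to 4. The call was lost with an estimated correlation (adjusted p = 0.865) and with limma's fry (adjusted p = 0.82). No member passed adjusted over the list alone (0 of 79), nor over all genes (0 of 79), and 8 had an unadjusted p under 0.05. Rpl9 had 0.26 ± 0.15 and Rpl23 had 0.23 ± 0.14. The median was 0.10 with DEHP in Cy5 and 0.10 with DEHP in Cy3, and the adjusted p of camera with the preset correlation was 0.000367 and 4.38e-07. With median centring in place of loess, the median was 0.27.

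Genes of oxidative phosphorylation had 59 of 79 members above 0 and 10 higher in all 4 pairs, with medians of 0.17, 0.0031, 0.12 and -0.022 in pairs 1 to 4. Atp5o, a subunit of ATP synthase, had 0.29 ± 0.15, and Uqcrfs1, the Rieske protein of complex III, had 0.16 ± 0.062. Without pair 1 the list median was 0.034 and camera no longer called it (adjusted p 0.124). It was not called with DEHP in Cy5 alone (adjusted p 0.0697, median 0.075), was called with DEHP in Cy3 alone (0.00593, median 0.051), and with median centring the median was 0.21. The call was lost with an estimated correlation (adjusted p = 0.865). Over the list alone, 0 of 79 members passed.

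Sertoli cell markers had 20 of 27 measured members above 0, with medians of 0.090, 0.10, -0.098 and 0.042 in pairs 1 to 4. Dhh was given above, and Defb19, a beta-defensin of the testis, had 0.26 ± 0.20. Clu, a secreted chaperone of Sertoli cells, had 0.11 ± 0.20, Inha, the alpha subunit of inhibin, had 0.093 ± 0.26, and Sox9, the transcription factor of Sertoli fate, had 0.028 ± 0.25 with an opposite sign in its other probe. Rhox5, an androgen-responsive homeobox gene, had -0.0047 ± 0.39, and Fshr, the receptor of follicle-stimulating hormone, had -0.014 ± 0.038. The camera adjusted p was 0.120 without pair 1 (median 0.026), 0.489 without pair 2 (0.034) and 0.284 without pair 4 (0.015), so that the call was lost in each, and 3.32e-05 without pair 3 (0.15). It was 0.197 with DEHP in Cy5 alone (median 0.077), 0.0777 with DEHP in Cy3 alone (0.068), 0.0918 with median centring (0.12), and 0.0993 with separate channels. The call was kept with no background correction (0.0191, median 0.081), the Agilent processed ratio (0.0484, 0.12), probes above background in all 16 channels (0.0422, 0.073), a dye term (0.0180, 0.039) and array weights (0.00486, 0.054). With an estimated correlation the adjusted p was 0.865. Over the list alone 0 of 27 members passed, with a smallest adjusted p of 0.0837.

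With the settings used, lists for germ cells and the other somatic cells of the testis were not called, and pair medians are given from here as mean ± SD over n = 4 pairs. Camera gained the elongating spermatid list (higher) with median centring (adjusted p 0.0213, median 0.19) and without pair 1 (0.00113, 0.13), and the round spermatid list (lower) without pair 2 (0.0298, -0.11). Both were absent with an estimated correlation over all pairs (adjusted p = 0.947 and 0.923), and over the settings the sign turned, with medians from -0.055 (without pair 4) to 0.19 and from -0.11 to 0.12 (median centring; 0.0090 without pair 4). Elongating spermatid markers had median 0.0014 (pair medians -0.0062 ± 0.28, 10 of 20 members above 0, adjusted p 0.884), with -0.42 in pair 1 against 0.076, 0.12 and 0.20. Spata3 had 0.24 ± 0.12 and Tnp2, a transition protein of sperm chromatin, had 0.13 ± 0.12. Round spermatid markers had median -0.043 (pair medians -0.045 ± 0.21, 5 of 21 members above 0, adjusted p 0.239), with -0.32 in pair 4. Catsper2 and Catsper4, sperm calcium channel genes, had -0.27 ± 0.39 and -0.17 ± 0.19. Spermatocyte and meiosis markers had median -0.039 (pair medians -0.018 ± 0.048, 8 of 27 members above 0, adjusted p 0.254); Aurkc, a meiotic kinase, had 0.29 ± 0.21 and Smc1b, a meiotic cohesin, -0.18 ± 0.19. Spermatogonia markers had median -0.070 (pair medians -0.037 ± 0.046, 1 of 11 members above 0, adjusted p 0.197), with Uchl1 at 0.25 ± 0.17 and Sohlh2 at -0.070 ± 0.039. Leydig markers had median -0.0093 (pair medians -0.0084 ± 0.053, 7 of 14 members above 0, adjusted p 0.884). Star and Cyp17a1, of steroid synthesis, had -0.21 ± 0.42 and -0.15 ± 0.14, and Igf1 had 0.25 ± 0.31. Insl3, a peptide hormone of Leydig cells, had -0.12 ± 1.65, with -0.98, 2.23, -1.49 and -0.25 in pairs 1 to 4. Peritubular myoid markers had median -0.047 (pair medians -0.035 ± 0.12, 3 of 10 members above 0, adjusted p 0.789), with Myl9 and Myh11, smooth muscle myosins, at 0.19 ± 0.26 and 0.16 ± 0.32. Macrophage and leukocyte markers had median -0.060 (pair medians -0.042 ± 0.081, 3 of 12 members above 0, adjusted p 0.288), with Fcgr3 at -0.093 ± 0.089 (its other probe opposite) and Adgre1 at -0.089 ± 0.12. Endothelial and blood markers had median -0.036 (pair medians -0.023 ± 0.040, 3 of 8 members above 0, adjusted p 0.967), with Egfl7 at 0.27 ± 0.25 and Flt1, a VEGF receptor, at -0.17 ± 0.19.

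With the settings used, lists for lipid, xenobiotic and redox metabolism were not called. Camera gained xenobiotic metabolism (higher) with no background correction (adjusted p 0.0191, median 0.095), with array weights (0.0406, 0.056) and without pair 3 (0.00371, 0.061), and glycolysis and lactate supply (lower) with array weights (0.0340, -0.090) and without pair 4 (0.00208, -0.14). Both were absent with an estimated correlation over all pairs (adjusted p = 0.923 each), and over the settings the medians ran from 0.012 (without pair 2) to 0.17 (Agilent processed ratio) and from -0.14 to -0.017 (median centring). Peroxisome proliferator-activated receptor (PPAR) targets and fatty acid oxidation had median -0.028 (pair medians -0.017 ± 0.076, 12 of 31 members above 0, adjusted p 0.884), with Cidec at 0.18 ± 0.17 and Ucp2 at 0.26 ± 0.29. Ppara and Pparg, the receptors, had 0.034 ± 0.21 and 0.011 ± 0.21. Xenobiotic metabolism had median 0.058 (pair medians 0.029 ± 0.10, 14 of 19 members above 0, adjusted p 0.239), with Gstm2, a glutathione transferase, at 0.37 ± 0.41 and Abcc3, an efflux pump, at 0.24 ± 0.29. Oxidative stress response had median 0.040 (pair medians 0.058 ± 0.043, 13 of 21 members above 0, adjusted p 0.197), with Gclc, of glutathione synthesis, at 0.27 ± 0.20 and Gpx1, a glutathione peroxidase, at 0.25 ± 0.19. Cholesterol biosynthesis had median 0.036 (pair medians -0.0025 ± 0.032, 14 of 25 members above 0, adjusted p 0.884). Fdft1, squalene synthase, had -0.32 ± 0.15 with an opposite sign in its other probe. Fatty acid synthesis had median 0.037 (pair medians 0.013 ± 0.021, 10 of 17 members above 0, adjusted p 0.884), with Fads3 at -0.25 ± 0.23 and Lpin1 at -0.24 ± 0.25. Glycolysis and lactate supply had median -0.041 (pair medians -0.089 ± 0.15, 5 of 18 members above 0, adjusted p 0.197), with Ldha, lactate dehydrogenase A, at -0.24 ± 0.14 and Slc2a3, a glucose transporter, at -0.30 ± 0.26.

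With the settings used, lists for Sertoli function and signalling were not called. Camera gained androgen-regulated Sertoli genes (higher) with array weights (adjusted p 0.00509, median 0.13), without pair 3 (0.0351, 0.15) and without pair 4 (0.0435, 0.13). The list was absent with an estimated correlation over all pairs (adjusted p = 0.865), and its median fell to 0.024 without pair 1. Androgen-regulated Sertoli genes had median 0.10 (pair medians 0.058 ± 0.094, 7 of 9 members above 0, adjusted p 0.129), with Corin at 0.10 ± 0.14 and Eppin (Spinlw1) at 0.20 ± 0.31. Blood-testis barrier and junction genes had median -0.037 (pair medians -0.037 ± 0.036, 9 of 24 members above 0, adjusted p 0.33), with Nectin3 (Pvrl3) at -0.14 ± 0.086 and Afdn (Mllt4), its cytoplasmic partner afadin, at -0.27 ± 0.24. The Sertoli cytoskeleton list had median -0.0047 (pair medians -0.015 ± 0.051, 9 of 21 members above 0, adjusted p 0.698), with Map4 at -0.38 ± 0.29 and Tubb5 at -0.34 ± 0.30 (other probe opposite). Retinoid signalling had median 0.0011 (pair medians -0.018 ± 0.032, 8 of 15 members above 0, adjusted p 0.967), with Lrat, which stores retinol as esters, at -0.14 ± 0.14 and Dhrs3, a retinal reductase, at 0.12 ± 0.17 (other probe opposite). Inhibin, TGF-beta and growth factors had median -0.018 (pair medians -0.0031 ± 0.052, 5 of 13 members above 0, adjusted p 0.884), with Igf2 at -0.26 ± 0.33. Hormone and nuclear receptors had median 0.00098 (pair medians -0.0021 ± 0.017, 13 of 26 members above 0, adjusted p 0.922), with Nr2c2 at -0.39 ± 0.45 and Nr1h2, the liver X receptor beta, at 0.12 ± 0.11.

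With the settings used, lists for stress, growth and immunity were not called. Camera gained cell cycle (lower) with no background correction (adjusted p 0.0191, median -0.082), with the Agilent processed ratio (0.0484, -0.12), with array weights (0.00343, -0.066) and without pair 4 (0.000499, -0.089), heat shock and unfolded protein response (lower) without pair 2 (0.0298, -0.078), and the proteasome (higher) with DEHP in Cy3 alone (0.0254, 0.046). All 3 were absent with an estimated correlation over all pairs (adjusted p = 0.865, 0.865 and 0.923). Over the settings the medians ran from -0.12 to -0.00017 (without pair 3) for cell cycle, from -0.095 (DEHP in Cy3 alone) to 0.033 (median centring) for heat shock and from -0.033 (DEHP in Cy5 alone) to 0.11 (median centring) for the proteasome. Heat shock and unfolded protein response had median -0.052 (pair medians -0.073 ± 0.084, 5 of 22 members above 0, adjusted p 0.129), with Hsp90aa1, a cytosolic chaperone, at -0.19 ± 0.083 and Canx, calnexin of the endoplasmic reticulum, at -0.19 ± 0.15. Apoptosis had median 0.015 (pair medians -0.0062 ± 0.0089, 13 of 23 members above 0, adjusted p 0.884), with Cflar, an inhibitor of caspase 8, at 0.21 ± 0.12 and Bbc3, the p53 target Puma, at -0.40 ± 0.31. Immediate early genes had median -0.0058 (pair medians 0.0038 ± 0.038, 8 of 18 members above 0, adjusted p 0.826), with Klf2 at -0.14 ± 0.080 (other probe opposite) and Klf4 at -0.33 ± 0.32. Cell cycle had median -0.055 (pair medians -0.050 ± 0.11, 8 of 29 members above 0, adjusted p 0.129), with Mcm4, of the replicative helicase, at -0.11 ± 0.079 and Ccne1, cyclin E1, at 0.18 ± 0.19. Interferon and antigen presentation had median 0.032 (pair medians 0.036 ± 0.046, 9 of 11 members above 0, adjusted p 0.254), with B2m, beta-2 microglobulin, at 0.18 ± 0.078 and Ifi35 at 0.057 ± 0.053. The proteasome list had median 0.0085 (pair medians 0.026 ± 0.044, 20 of 36 members above 0, adjusted p 0.582), with Psmb4 at 0.41 ± 0.32 and Psmb6 at 0.21 ± 0.16. Across the 29 lists, 0 members passed either over all genes or adjusted over the list alone. The sign of Cyp17a1, Adgre1, Canx, Ldha and Mcm4 was positive with DEHP in Cy5 alone, that of Nectin3 and Klf2 with DEHP in Cy3 alone, and that of Nectin3, Klf2 and Hsp90aa1 with median centring.

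**Figure D2:**
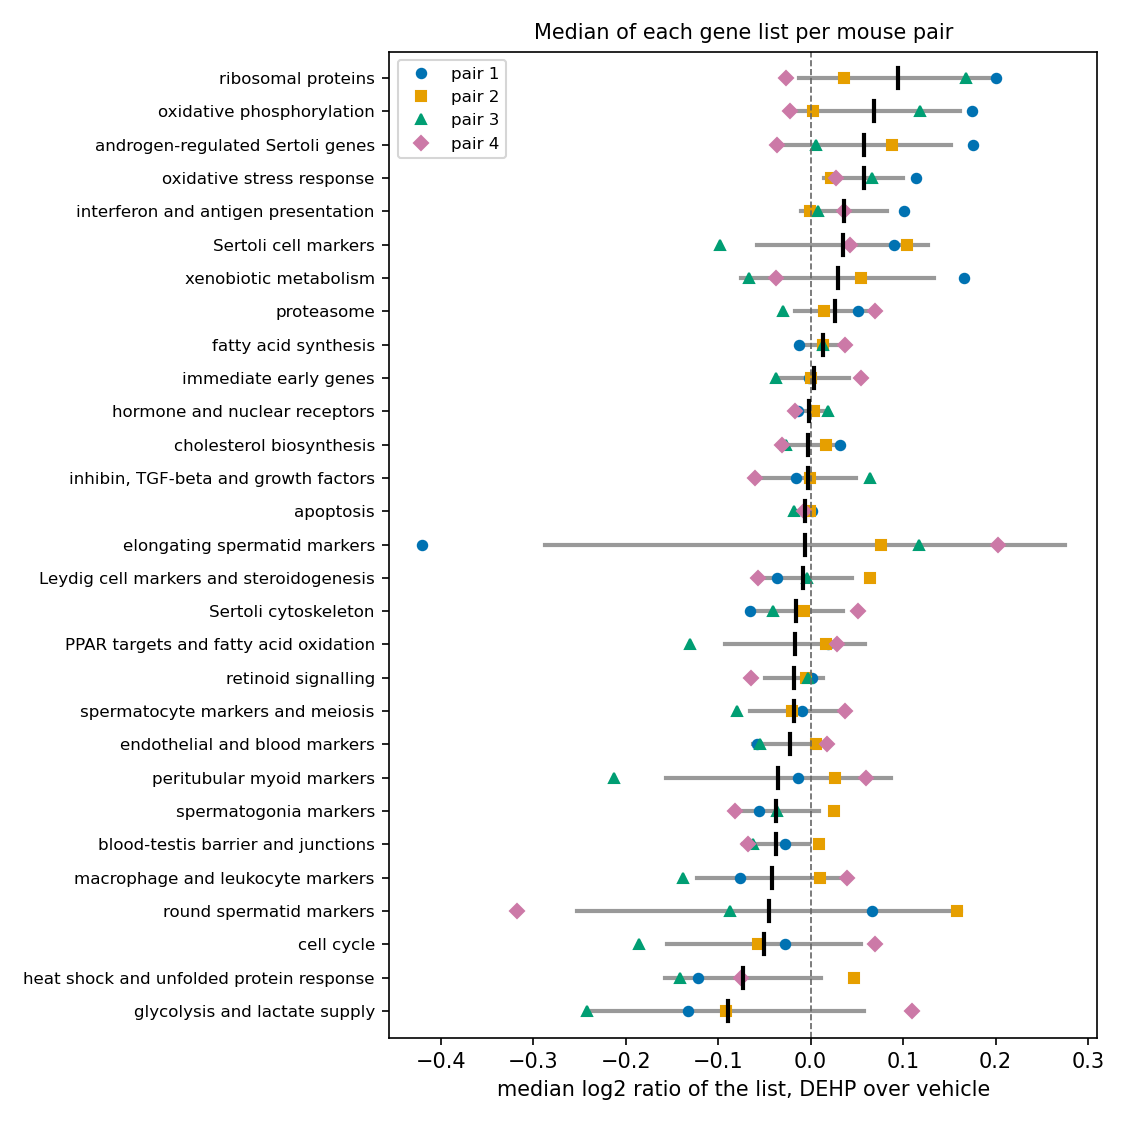
Median log2 ratio of DEHP over vehicle (x axis) of each of the 29 gene lists. Points are the medians of the 4 mouse pairs, the black tick is their mean and the grey bar is 1 SD between pairs; ribosomal proteins, called by camera with the preset correlation, had 0.20, 0.037, 0.17 and -0.026 in pairs 1 to 4.

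Sizes were small in the main fit. Of the 22975 probes, 0 had a mean ratio over 2-fold and 14 over 1.5-fold, and the 95% interval lay within 2-fold for 99.7% of probes. The offset of 50 pulls ratios of dim spots towards 0, and the median net signal per channel was only 37.6 to 71.4. These sizes thus hold for this setting. With the Agilent processed ratio the median of Sertoli markers was 0.12, against 0.039, while that of ribosomal proteins was 0.11, against 0.10. At an unadjusted p under 0.05 there were 1054 probes (4.59%, 528 higher and 526 lower), where chance gives 1149. The sign was shared by all 4 pairs in 3135 probes (13.6%), where chance gives 12.5%. The deposited log2 ratios of the authors, for 16095 spots with 526 to 852 missing values per array, also gave 0 calls, with 770 at an unadjusted p under 0.05. With 4 pairs, 200 simulated changes of 1.41-fold gave 0% recovery and 2-fold changes gave 82%. The simulated probes were independent and equally variable in all pairs. In the data the SD of the log2 ratio across probes ran from 0.13 in pair 2 to 0.27 in pair 4. The recovery in these data may thus differ from these shares. The capture protocol in the labels speaks of Leydig cells while the tissue label gives Sertoli-cell-rich areas, so the cell content of the captured areas is not settled by the labels. Mean log2 intensity reached 17.9 for spermatid genes (Prm2), 13.8 for Sertoli markers (Cst9) and 14.0 for Leydig markers (Fdx1). Each list also held dim members (Akap3 7.99, Gata1 7.06, Star 7.65). The captured RNA thus held germ-cell RNA, but intensities of different probes do not give the share of a cell type.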

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

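The 3 results here were found by a fixed rule on gaps, set before the data were examined and applied to 89 named genes and 29 lists. Chance flags about 5% of groups of 4 independent normal values, and 1 gene and 2 lists were found. Most named genes were chosen for a small p, which favours close values of the pairs, so 1 of 89 genes cannot be set against that share. Acot13 had a log2 ratio of 0.69 in pair 1 and 0.28 to 0.33 in the other pairs. PPAR targets and fatty acid oxidation had a median of -0.13 in pair 3 and 0.017 to 0.028 in the other pairs. Retinoid signalling had a median of -0.065 in pair 4 and -0.0046 to 0.0017 in the other pairs.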

How the results depend on the processing

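In 0 of the 18 settings of the fit did a probe pass, with counts at an unadjusted p under 0.05 of 496 (without pair 3) to 2425 (DEHP in Cy3 alone) and smallest adjusted p of 0.443 to 1.00; without pairs 1, 2, 3 and 4 these counts were 555, 1460, 496 and 1929. Aquantile, the filter and variance settings, the dye term and the separate channels move no ratio, so they test nothing there. The number of lists called was 3, against 5 with no background correction, 1 with DEHP in Cy5 alone and 7 with array weights. It was 0 with an estimated correlation, 0 with fry, and 2 to 5 with a pair left out. The preset correlation was 0.01. The estimated one was higher in all 3 called lists. It was 0.27 for ribosomal proteins, 0.12 for oxidative phosphorylation and 0.17 for Sertoli cell markers. The calls with the preset thus rest on a correlation below that estimated from the data. For the other settings the cause was not tested. The number of lists called was 3 with a dye term and the mouse pair as a replicate block (1538 probes at an unadjusted p under 0.05, 0 calls). That is also the fit with slide as a block, and within-slide values are those of single dye orientations. Mice that share a number did not deviate together from their group means (correlations across probes of -0.20, -0.35, -0.046 and -0.024). Partners on an array had 0.13, 0.30, 0.041 and 0.050 in pairs 1 to 4. Deviations within a group sum to 0, so effects shared on an array can lower the first values. Whether the number pairs mice is thus not settled. With separate channels, the fit with the number as a replicate block called 0 probes and 2 lists, as did that without it.

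Over the 10 settings that move ratios, 570 of 580 values of 80 named genes kept their sign, and 0 passed. Left-out pairs were not counted for genes with 1 sign in all 4 pairs, which cannot turn. The other 9 named genes, fixed by name, were compared by size only, so turned signs among them are not listed. Of their 152 values over all alternatives, 149 moved by under 1 SD. Among the 80, the sign turned with DEHP in Cy5 alone for Cyp17a1 (0.076), Adgre1 (0.077), Canx (0.065), Ldha (0.24) and Mcm4 (0.078). It turned with DEHP in Cy3 alone for Nectin3 (0.037) and Klf2 (0.082). With median centring it turned for Nectin3 (0.044), Klf2 (0.0050) and Hsp90aa1 (0.037). Ratios of 1 dye orientation keep the dye effect that averaging cancels. In the limma fit with a dye term, 5745 probes (25.0%) had a dye term at an adjusted p under 0.05. What caused the turn of each gene was not tested. List medians moved by under 1 SD in 277 of 319 values under the 11 settings that move them. The deposited ratios gave 0 calls; named genes and lists were not run on them.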

Other observations

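Of the tests here, those chosen only after the result was seen were the ones on a single pair, on sign patterns of lists and probes, on probes called in splits of the mice, on the 3 called lists in these splits, on a single unusual mouse, on Leydig RNA, on the X chromosome and on the most variable genes. The 20 genes that varied most between pairs included Insl3, treated below, and several others. Selenop had 1.33 in pair 2 and -1.40 in pair 3, Fabp3 1.27 and -0.98, Ptgds 1.06 and -0.93, Agt 1.16 and -0.73, and Lyz2, lysozyme of macrophages, 0.84 and -1.72. Slpi, a secreted protease inhibitor, had 1.97, 0.020, 1.81 and 0.053 in pairs 1 to 4. Its mean log2 ratio of 0.96 was the largest of all probes tested (unadjusted p 0.070 in limma). Relative to its mean over the mice, it lay at 1.80 and 1.19 in DEHP mice 1 and 3. In the other DEHP mice and all vehicle mice it lay at -0.62 to -0.17. On the X chromosome, 17 of 549 genes had an unadjusted p under 0.05 in limma with a higher ratio and 2 with a lower one, against 405 and 390 of 16420 other genes. The other genes include those without a position in the design, some of which may lie on the X chromosome. With the sign of pair 4 turned, the X counts were 48 and 7, where 2438 probes in all had such a p, against 1054 as labelled. With the signs of pairs 2 and 3 turned, they were 4 and 28, among 1058 probes.

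Between mice, the elongating list lay at percentile 0 of intensity-matched random lists in pair 1 and the round list at percentile 0.02 in pair 4. A shift of all abundant genes left after loess does not give this. Loess had already removed a trend with intensity within each array, so an earlier shift was not tested. The pair tested was also the one with the most extreme median of each list, which made a low percentile hard to avoid. DEHP mouse 1 had the lowest level of the elongating list (-0.13) and vehicle mouse 2 the highest (0.26), with a largest gap of 0.172 of the range, too small to single out a mouse.

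With the preset correlation, ribosomal protein and oxidative phosphorylation genes were higher in DEHP, though pair 4 was negative (-0.026 and -0.022) and both calls were lost with an estimated correlation (adjusted p = 0.865 each). A shift of all abundant genes left after loess is argued against, as both medians lay at percentile 100 of intensity-matched random lists. Loess had already removed a trend with intensity within each array, so an earlier shift was not tested. With median centring in its place the medians were 0.27 and 0.21. GC content of the probes is also argued against, as the medians were 0.10 and 0.076 after its trend was removed. A single pair did not carry the ribosomal list, whose lowest median with a pair left out was 0.081 and whose second highest percentile over the pairs was 100. For oxidative phosphorylation this stays open: that percentile was 99.94, but without pair 1 the median was 0.034, under the bound set for the leave-out test, and the percentile test was added after that result. A DEHP effect stays open. With the labelled signs 3 lists were called, 6 of the 8 sign patterns of the pairs gave as many (highest other 6), and 8 patterns are too few for a share under 0.05.

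Pair 4 ran against the others, with correlations across probes of -0.075, -0.32 and -0.067 with pairs 1, 2 and 3. An exchange of DEHP and vehicle in its labels may be considered: turning its sign gave 2438 probes at an unadjusted p under 0.05, against 1054 as labelled and at most 1296 in the other patterns, as the exchange needs. The test was written before the counts but after these correlations were seen, which made that outcome hard to avoid, and 1 of 8 patterns is always highest. Both arrays of the pair carry matching labels, and ordinary differences between mice remain open, so no exchange is shown.

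Insl3 varied in both groups. Error of single spots is argued against in pairs 1 to 3, the 3 largest, where the dye orientations differed by at most 0.14 of the pair mean, but not in pair 4, where they differed by 0.69 of a mean of -0.25. Another amount of Leydig cell RNA might be a source and stays open: over 8 mice the median r of the 13 other Leydig list genes with Insl3 was -0.0069 (exact permutation p 0.954), with a median rho of 0.048 (exact permutation p 0.764), within -0.31 to 0.24 for random lists and -0.25 without DEHP mouse 1 and vehicle mouse 3. That value met the bound first set against this source (not above 0), but 6 genes were positive and the rest negative, so the bound was changed afterwards and a further test added, in which the list lay at percentile 99.64 in pair 2 and 68.93 in pair 3. Of the 13 genes, 3 were positive in pair 2 and negative in pair 3 as Insl3 was (Hsd3b1, Star and Vcam1), 2 were the reverse (Srd5a1 and Tspo) and 8 had the same sign in both. Relative to its mean over the mice, Hsd3b1 had the sign of Insl3 in each of the 8 mice, while Star and Cyp17a1 did not. Outside the list, Selenop, Fabp3, Ptgds, Agt and Lyz2 also had the signs of Insl3 in pairs 2 and 3. These genes were picked for their spread, so they do not settle the source.

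With separate channels, chance was not excluded for the counts: 21 of the 35 splits of the 8 mice gave as many called lists as the real split (2, highest other 6), and 25 of 35 gave as many probes at an unadjusted p under 0.05 (860, highest other 2760). The highest split exchanged DEHP mouse 4 and vehicle mouse 3, and the exchange of DEHP mouse 2 and vehicle mouse 2 gave 2273. Both put array partners on the same side, so effects shared by the channels of an array do not cancel in them. The exchange of the partners of pair 4 gave 1921, the highest among splits that keep all partners apart. That repeats the sign patterns above on the same arrays, so it adds no separate support. In any set 1 split is always highest, and no cause was tested. A camera p as small as that of the real split was found by permutation in 3 of 35 splits for ribosomal proteins (7.36e-11, smallest other 5.46e-22). For oxidative phosphorylation it was 6 of 35 (1.22e-05, smallest other 1.02e-10) and for Sertoli cell markers 12 of 35 (0.0103, smallest other 2.53e-12). Many of these splits put array partners on the same side. Among splits that keep all partners apart, the real split had the smallest camera p for ribosomal proteins (next 4.72e-09). It did not for oxidative phosphorylation (smallest other 8.98e-07) or Sertoli cell markers (smallest other 9.90e-08). Such splits are too few for a share under 0.05, so chance was not excluded for these lists. For probes past the threshold the real count was 0, which 35 of 35 splits (highest other 1) and 8 of 8 sign patterns (highest other 0) must reach, so these counts test nothing.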
